A study of Hordeum vulgare with 21 samples.

How the data were processed

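RNA from whole grains of Hordeum vulgare cultivar Conrad was sequenced at 7 stages of small-scale malting with 3 replicates each, 21 libraries in all. Per the labels, 5 grain samples from 4 growing regions were pooled and mixed, and each of 3 malting runs took 110 g dry weight from the pool. Steeping lasted 38 h, in alternation of 4 h under water at 16 °C and 4 h of air rest at 18 °C, to a moisture of 45%. Germination lasted 120 h at 17 °C with a collection every 24 h. Per the labels' protocols, libraries were made from poly-A selected RNA with a kit that keeps the strand (Illumina TruSeq Stranded mRNA).

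The authors deposited expected counts per gene, which are estimated read counts that need not be whole, and TPM, transcript abundances that sum to the same total in each library. STAR and RSEM are named in the submitters' processing notes, with no version or role. The genome build, the annotation, the strand setting of the counting and any filter on reads are not given in the sources used here, and no coordinates were used. Chromosome codes are part of the IDs, which start with HORVU.MOREX.r3. Expected counts were rounded to whole numbers before the count tests. Fractional expected counts mark reads shared between similar genes or transcripts of different genes, and 3809 of the 20637 tested genes, or 18.5%, had a count further than 1e-09 from a whole number in at least 1 library. The 4 named IDs had whole counts in all libraries.

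None of the 35826 IDs matched the reference table of 58438 genes (assembly MorexV3_pseudomolecules_assembly), which holds symbols of another naming system. The 36 gene lists fixed in advance, 6 of them marker lists of grain tissues, were to be matched by gene name. Their set tests and their shares of TPM were therefore not run. In their place, and chosen after the data were seen, genes were grouped by the stage of their highest mean CPM and by their direction at steeping, and the shares of the 10 and 100 most abundant genes were computed. The rule for named genes in the absence of names took the 2 rising and 2 falling IDs with the largest absolute log2 fold change from dry grain to day 5. They had to have an adjusted p under 0.05, a mean of at least 50 CPM at the higher stage and no overlap between replicates. Comparisons, their tests, gene lists, this rule and most alternatives were fixed before the data were examined. The permutation tests of transcript pool measures were not.

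Genes were filtered with filterByExpr by stage (minimum count 10 in 3 libraries, minimum total 15), which kept 20637 genes, with a lowest share of 99.9% of the counts of a library after rounding, and left out 15189, of which 8132 had no count in any library. Library sizes were scaled by TMM. One quasi-likelihood model of 7 stage means was fitted to the 21 libraries (edgeR 4.0.16 in R 4.3.3), so that all stages share one estimate of the spread. From it came 1 F-test over the 7 stages and 8 comparisons: the 6 consecutive steps, day 5 against out-of-steep grain and day 5 against dry grain. Comparisons of day 5 with days 2 and 3 were added after the data were seen. P-values were adjusted by Benjamini-Hochberg over the tested genes within each comparison, 0.05 was the threshold, and no minimum fold was required. Standard errors of log2 fold changes were derived as the absolute log2 fold change divided by the square root of its F statistic. CPM of named IDs use TMM-scaled library sizes, and log2 CPM use a prior count of 2. A fitted fold change against a stage without counts depends on the default prior of the fit, which is separate from that prior count of 2. A floor of 3 counts per library was used for the fold of such an ID.

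Replicates of the malted stages are separate malting runs of one grain lot, and those of dry grain are unmalted, with no malting run behind them. P-values therefore measure the spread between malting runs and between dry grain samples, which may be technical, and not between crops or cultivars. No 2 libraries of a stage agreed within sampling noise: chi-square per degree of freedom between replicate pairs ran from 8.49 to 126, and Pearson's r of log2 CPM across genes from 0.957 to 0.991. The median SD of log2 CPM between replicates, over genes with at least 1 CPM at the stage, was 0.30 in dry grain, 0.19, 0.21, 0.11, 0.13 and 0.11 at days 0 to 4 and 0.21 at day 5. The labels do not say that a replicate letter follows one malting run through the stages, and letters were not used as a block. Sequencing batches are not given in the sources used here.

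Relative transcript length was the median over libraries of expected count over TPM, divided by each library's median ratio, from genes with at least 10 counts and 0.5 TPM. It was obtained for 20472 of the tested genes. The length correction removed from each library a smooth trend of log2 CPM over log2 length (lowess, span 0.3) through an offset in the same model.

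The fit was tested on simulated data with 200 genes changed among 20637, 50 for each fold. The changed genes were drawn from those with a mean of at least 1 CPM over the 2 stages, so recovery of lower genes was not tested. For the steeping comparison it recovered 28% of 1.5-fold, 58% of 2-fold, 94% of 4-fold and 90% of 8-fold changes, with 5 false calls. For the fourth day it recovered 14%, 52%, 84% and 98%, with 2 false calls, for the third day 16%, 58%, 88% and 100%, with 6, and for the fifth day 22%, 64%, 92% and 94%, with 6. Each simulated gene had the same spread at all stages. In the data the median SD between replicates was 0.30 in dry grain and 0.11 at day 4. The simulated recovery and false calls do not cover a spread that differs between stages. With a length trend put into the dry libraries, the corrected fit recovered 97% of 4-fold changes with 6 calls among the other genes, and the uncorrected fit made 4541. The correction used the same lengths that shaped the simulated trend, and the changed genes were drawn without regard to length. Whether the correction also removes real changes that go with length was therefore not tested. The simulated trend was stronger than that of the data. Spearman's rho of fold change with length was 0.779 among the other genes of the uncorrected fit, against 0.367 in the steeping comparison. These numbers of calls therefore do not carry over to the data.

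Alternatives were DESeq2 1.42.0, its size factors within edgeR, library size without composition scaling, no filter on low counts, limma 3.58.1 on log2(TPM + 1) and on log2(TPM + 0.1) for genes with at least 1 TPM in 3 libraries, limma without that filter, a minimum of 2-fold, replicate letters as a block, only the 6 libraries of the stages compared, and each library left out in turn. A fold change from limma is on the log2(TPM + pseudocount) scale, which understates the change of low genes. The length correction and a restriction to the genes with whole counts were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.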

Results

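Whole grains of the barley cultivar Conrad, a 2-row spring type bred in North America for malting, were followed through a small-scale malting run by poly-A selected RNA sequencing. Malting turns dry grain into partly germinated grain in 3 phases, steeping in water, germination in moist air and drying in hot air, and grain that had been dried in hot air was not analysed here. The 7 stages were dry unmalted grain (Dry), grain taken out of the steep (DoG0) and grain after 1 to 5 days of germination (DoG1 to DoG5). Each stage had 3 libraries, replicates A, B and C, which makes 21 libraries. The malted stages came from 3 separate malting runs of 110 g of one pooled grain lot, and the dry libraries from unmalted grain. Total expected counts per library ran from 18145400 (DoG5 replicate C) to 31582116 (DoG1 replicate C), and the dry grain libraries held 18783859 to 25488566. At these depths 3 counts in a library correspond to 0.095 to 0.165 CPM, counts scaled to a common library size, by total count. With the TMM-scaled sizes used for named IDs the mean was 0.170 CPM in dry grain. These limits cover counting error only. Of 35826 genes in the tables, 27694 had a count in at least 1 library and 20637 passed the filter on low counts and were tested.

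The files do not pair gene IDs with names, so genes are described by the stage at which they were highest and by their direction at each step, and 4 IDs are named. Transcripts of 18992 of the 20637 tested genes, or 92.0%, changed across the 7 stages (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05), and 1645 did not pass. The first principal component of log2 CPM held 52.0% of the variance and the second 22.6%. Dry, out-of-steep and 1-day grain lay apart from one another on these components, and grain of days 2 to 5 lay close together.

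**Figure D1:**
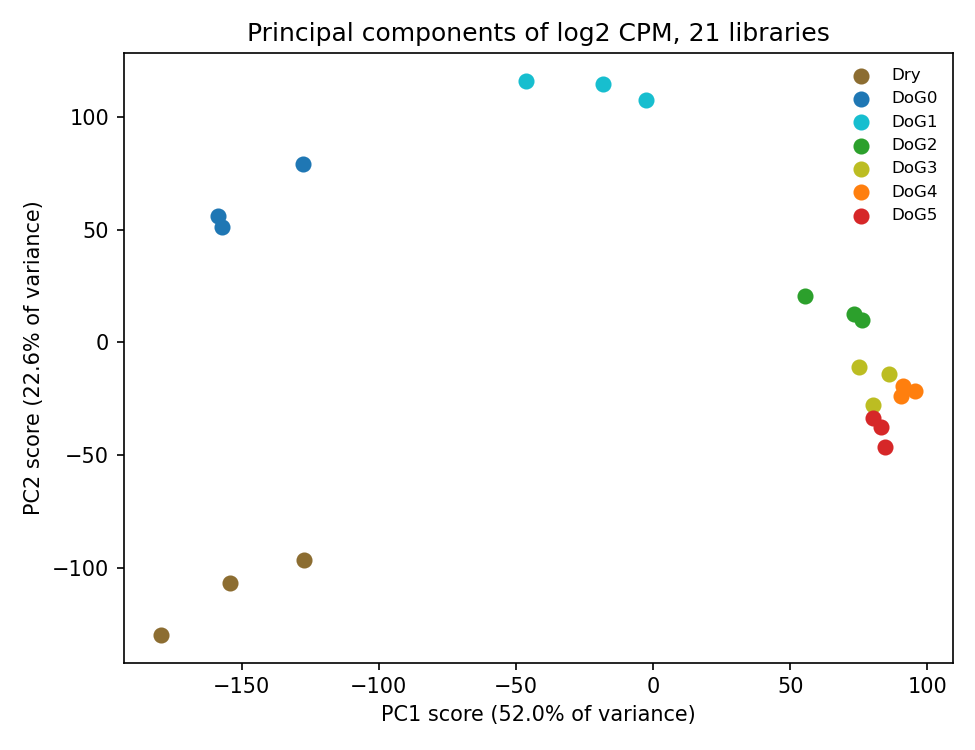
Scores of the 21 libraries on the first (horizontal, 52.0% of the variance) and second (vertical, 22.6%) principal components of log2 CPM, 1 point per library, coloured by stage. The libraries of days 2 to 5 all score between 55.3 and 95.5 on the first component, above every library of dry, out-of-steep and 1-day grain.

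The transcript pool of dry grain was concentrated in few genes and spread out on steeping. The 10 most abundant genes of each library held 19.3% ± 5.28 of all TPM in dry grain, 8.21% ± 0.655 out of the steep and 4.73% ± 0.174 after 1 day (SD, n = 3 each). From day 2 to day 5 the share lay between 6.04% and 6.38%. By expected counts it was 12.1% ± 3.88 in dry grain, 6.71% ± 0.657 out of the steep and 4.48% ± 0.319 at day 1, and it went from 5.53% ± 0.224 at day 2 to 4.40% ± 0.136 at day 5, so whether day 5 lay above day 1 depended on the unit. The 100 most abundant genes held 35.1% ± 6.27 in dry grain and 19.2% ± 0.577 at day 1 (SD, n = 3 each). The number of genes that together made up 50% of TPM was 366 ± 135 in dry grain, 797 ± 70.9 out of the steep, 919 ± 40.7 at day 1 and 695 ± 64.4 at day 5. Libraries held a count for 21099 ± 71.3 genes in dry grain, 21889 ± 90.7 out of the steep and 23025 ± 346 at day 1, with the depth of the libraries not equalised. All 4 measures differed between the 7 stages in permutation tests over 21 libraries, for a difference in any direction, with 100000 resamples. These tests were not planned before the data were examined. They treated the 21 libraries as independent, although the malted ones came from 3 malting runs. The adjusted p was 2e-05 for the 10-gene share and for the genes making up 50% of TPM, both from the smallest p the resamples can give, and 9e-05 and 2.67e-05 for the 100-gene share and the genes with a count. The dry libraries differed among themselves, with 10-gene shares of 25.4% in replicate A, 15.7% in B and 16.9% in C.

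The 18992 changed genes were assigned to the stage of their highest mean CPM, and genes highest in dry grain formed the largest of the 7 groups with TMM scaling. This group of 5527 genes held 67.2% ± 5.87 of TPM in dry grain, 36.0% ± 1.27 out of the steep and 29.2% ± 0.985 at day 1, and still held 32.4% ± 0.545 at day 5 (SD, n = 3 each). The 3950 genes highest out of the steep went from 11.9% ± 1.48 of TPM in dry grain to 35.2% ± 2.33 out of the steep, and then to 23.0% ± 1.60 at day 1 and 15.1% ± 0.724 at day 2. The 2934 genes highest at day 1 had 4.41% ± 1.05 of TPM in dry grain, 16.5% ± 0.805 at day 1 and 7.11% ± 0.158 at day 5. The 1587 genes highest at day 2 reached 18.7% ± 0.505 there and had 12.0% ± 0.222 at day 5. Groups of 1142 and 1481 genes were highest at days 3 and 4 and held 9.80% ± 0.232 and 7.52% ± 0.431 of TPM at those stages. The 2371 genes highest at day 5 had 3.53% ± 0.156 of TPM out of the steep, 8.89% ± 0.438 at day 2, 13.7% ± 0.380 at day 4 and 16.1% ± 0.317 at day 5. Because the groups were chosen on the same libraries, their rise to the stage that defines them is not independent evidence and was not tested. The F-test called a difference between any stages, and no test set a gene's highest stage apart from the others. In the reported fit 31 genes changed on the fourth day and 26 on the fifth. Most genes grouped under days 3 to 5 were therefore not told apart from an adjacent day. The groups also differed in transcript length, described with the steeping step: the median relative length was 0.790 in the group highest in dry grain and 1.28 in the group highest out of the steep. Group sizes varied with the processing: 4017 genes were highest in dry grain and 4116 at day 1 with scaling by library size only, and 2278 and 4616 with limma on log2(TPM + 1). With the length trend removed 6571 genes were highest in dry grain, and without Dry replicate A 5076.

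**Figure D2:**
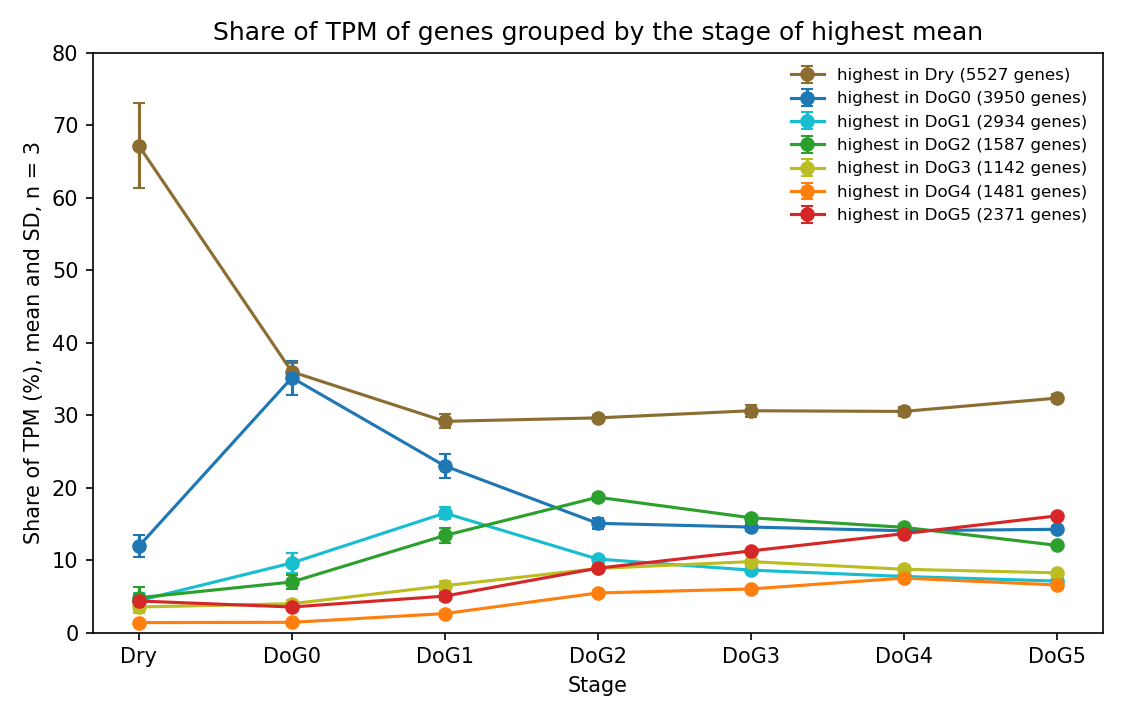
Share of TPM (vertical, percent) at the 7 stages (horizontal) for genes grouped by the stage of their highest mean CPM; points are means of 3 libraries and bars are SDs. The group highest in dry grain falls from 67.2% to 36.0% on steeping, and the group highest at day 5 climbs from 3.53% out of the steep to 16.1%.

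Steeping was assessed by comparing grain out of the steep with dry grain, 38 h apart. Of the tested genes, 6027 rose and 6601 fell, 12628 or 61.2% in all. Among these, 3720 rose and 3971 fell by at least 2-fold, and 636 rose and 689 fell by at least 8-fold. The median log2 fold change was 1.22 among the genes that rose and -1.21 among those that fell. With only the 6 libraries of the 2 stages 9623 genes changed, and 9562 of the 12628 kept their call and direction. Transcripts present in dry grain at 1 CPM or more and without a count in any out-of-steep library came from 18 genes, and the reverse held for 20 genes. Of the named IDs, HORVU.MOREX.r3.1HG0054710 fell from 3828 ± 2998 CPM, with 7290 CPM in replicate A, to 386.9 ± 62.6 CPM (SD, n = 3 each; log2 fold change -3.31, SE 0.37, edgeR adjusted p = 5.59e-07).

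Longer transcripts rose and shorter ones fell over the steep. Relative transcript length, recovered from the ratio of expected count to TPM, was known for 20472 of the 20637 tested genes. The median log2 fold change in 5 equal groups of genes ordered by length was -0.72 in the shortest group, -0.45, -0.15 and 0.11 in the next 3 and 0.74 in the longest. Spearman's rho between fold change and length was 0.367 across genes, which are not independent replicates. It was -0.0945 on the first day and between -0.0392 and 0.0426 on the other 4 days. The genes that rose had a median relative length of 1.37 and those that fell 0.806. The direction of change was relative to the pool: with scaling by library size only 7230 genes rose and 5248 fell, and with limma on log2(TPM + 1) 9386 rose and 3018 fell, settings under which the median log2 fold change of all genes was 0.17 and 0.41, against -0.02 in the reported fit. With the length trend removed 5194 rose and 6650 fell, and 9714 of the 12628 changed genes kept their call and direction.

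**Figure D3:**
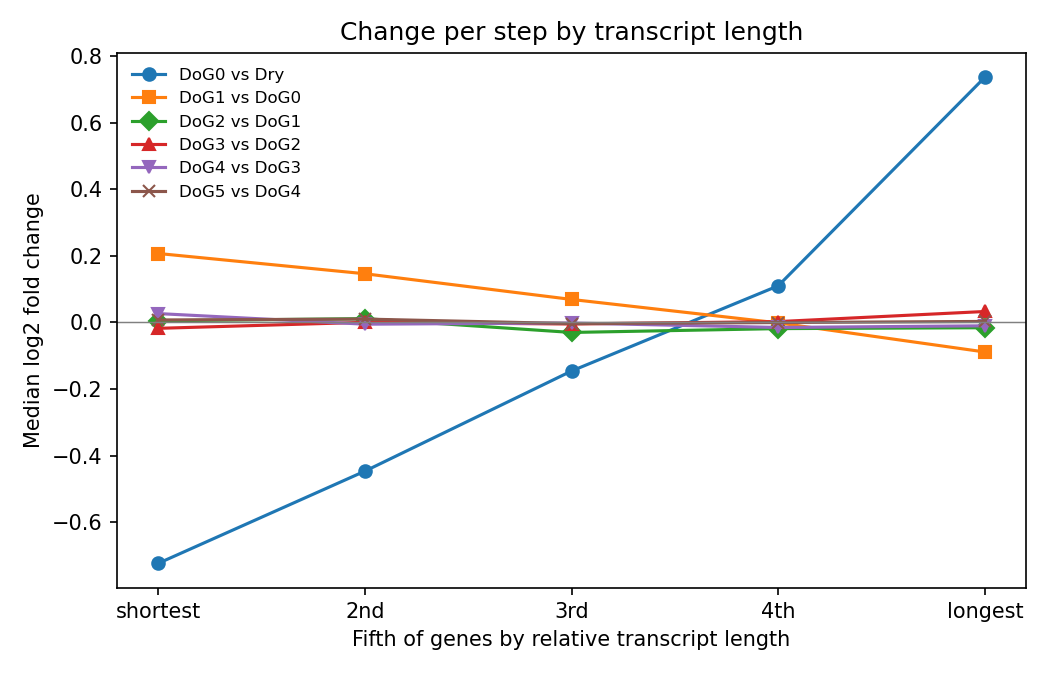
Median log2 fold change (vertical) in 5 equal groups of genes ordered by relative transcript length (horizontal) for the 6 consecutive steps, 1 line per step. From dry to out-of-steep grain the median runs from -0.72 in the shortest group to 0.74 in the longest, and it stays between -0.09 and 0.21 at every other step.

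The first day of germination again moved over 50% of the tested genes. Relative to grain out of the steep, 5851 genes rose and 4920 fell by day 1, 10771 or 52.2% of those tested. Large rises outnumbered large falls: 3690 genes rose and 1736 fell by at least 2-fold, and 1162 rose and 109 fell by at least 8-fold. The median log2 fold change was 1.39 among genes that rose and -0.79 among those that fell. HORVU.MOREX.r3.1HG0054710 fell to 17.3 ± 1.80 CPM (log2 fold change -4.48, SE 0.39, edgeR adjusted p = 3.02e-07), and HORVU.MOREX.r3.7HG0653340, which had 288.5 ± 89.1 CPM out of the steep, fell to 65.3 ± 16.7 CPM (log2 fold change -2.14, SE 0.49, adjusted p = 0.00152; SD, n = 3 each). With scaling by library size only, 6714 genes rose and 3692 fell, and with the length trend removed 5271 rose and 5809 fell.

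On the second day 4057 genes rose and 3515 fell, 7572 or 36.7% of those tested. Of these, 2072 rose and 1860 fell by at least 2-fold, and 471 rose and 286 fell by at least 8-fold. Both named rising IDs rose at this step, and HORVU.MOREX.r3.7HG0747470 had also risen on the first day, from 1 count to 23 counts over 3 libraries (log2 fold change 3.96, SE 1.39, edgeR adjusted p = 0.0259). HORVU.MOREX.r3.1HG0000260 went from 0.340 ± 0.335 to 22.03 ± 9.16 CPM (log2 fold change 6.16, SE 0.58, edgeR adjusted p = 5.52e-07). HORVU.MOREX.r3.7HG0747470 went from 0.297 ± 0.336 to 10.9 ± 5.73 CPM (log2 fold change 5.36, SE 0.54, adjusted p = 2.5e-06). HORVU.MOREX.r3.7HG0653340 fell to 1.82 ± 2.38 CPM (log2 fold change -5.18, SE 0.59, adjusted p = 4.21e-06; SD, n = 3 each). With scaling by library size only 3253 genes rose and 4534 fell, and with limma on log2(TPM + 1) 2869 rose and 4926 fell, so the direction of the majority turned with the scaling.

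Genes moved by steeping often moved in the opposite direction on the second day, a comparison that shares no library with the first. The second-day change is measured against day 1, so it may undo a first-day change and not the change at steeping. These cases were not told apart. Of the 6027 genes that rose at steeping, 1756 fell and 388 rose on the second day, where independent lists of these sizes would share 1027 and 1185. Of the 6601 that fell at steeping, 2394 rose and 463 fell on the second day, against 1298 and 1124 for independent lists. On the third day 146 of the genes that had fallen at steeping rose and 30 fell, against 75.5 and 55.3, and 59 of those that had risen fell and 18 rose, against 50.5 and 68.9. Relative to dry grain, the median log2 level of the genes that rose was 1.20 ± 0.02 out of the steep, 1.04 ± 0.04 at day 1, 0.77 ± 0.03 at day 2 and 0.67 ± 0.05 at day 5. That of the genes that fell was -1.12 ± 0.03, -1.01 ± 0.07, -0.73 ± 0.02 and -0.62 ± 0.04 at the same stages (SD over 3 libraries). Both groups were called on the dry and out-of-steep libraries, so their out-of-steep medians follow in part from the choice of genes, and how much of the later return does was not tested. By at least 2-fold at both steps, 761 genes rose and then fell, 92 rose and rose again, 1023 fell and then rose and 166 fell and fell again. Without a minimum fold these 4 numbers were 1756, 388, 2394 and 463 in the reported fit. They were then 3375, 420, 1200 and 263 with limma on log2(TPM + 1), and 1773, 306, 2427 and 522 with the length trend removed. The 463 genes that fell at both steps became 282 without DoG1 replicate B and 286, 276 and 291 without DoG2 replicates A, B and C.

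Few genes passed the test between consecutive days after the second. On the third day 236 genes rose and 173 fell, 409 in all or 1.98% of those tested, and 124 of them rose and 99 fell by at least 2-fold. On the fourth day 3 genes rose and 28 fell, and on the fifth day 22 rose and 4 fell. The median absolute log2 fold change of all tested genes was 0.86 at steeping, 0.61, 0.44, 0.22 and 0.19 on days 1 to 4 and 0.16 on the fifth day. Pearson's r between stage means of log2 CPM across genes was 0.911 over the steep, 0.926 and 0.933 on days 1 and 2, and 0.984, 0.990 and 0.990 on days 3, 4 and 5. The named IDs HORVU.MOREX.r3.1HG0000260 and HORVU.MOREX.r3.7HG0747470 rose on the third day, to 77.4 ± 35.4 CPM (log2 fold change 1.81, SE 0.40, edgeR adjusted p = 0.0287) and 34.4 ± 8.79 CPM (1.66, SE 0.38, adjusted p = 0.038). No named ID passed the test on day 4 or day 5.

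The counts of the last 3 days differed between the ways of fitting them. With only the 6 libraries of each step, 2440, 1163 and 11 genes changed on days 3, 4 and 5, and with DESeq2 1092, 215 and 139. Of the 409 genes of the third day, 395 were called in the same direction with the 6 libraries alone, as were 30 of the 31 of the fourth day and 9 of the 26 of the fifth. Leaving out any 1 library of the step left 79 to 174 genes on the third day, 1 to 8 on the fourth and 6 to 36 on the fifth, where 9, 6 and 7 genes were left without DoG4 replicates A, B and C and 8 without DoG5 replicate B. On the fourth day scaling by library size only gave 4 genes that rose and 14 that fell, and limma on log2(TPM + 1) gave 30 and 15.

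**Figure D4:**
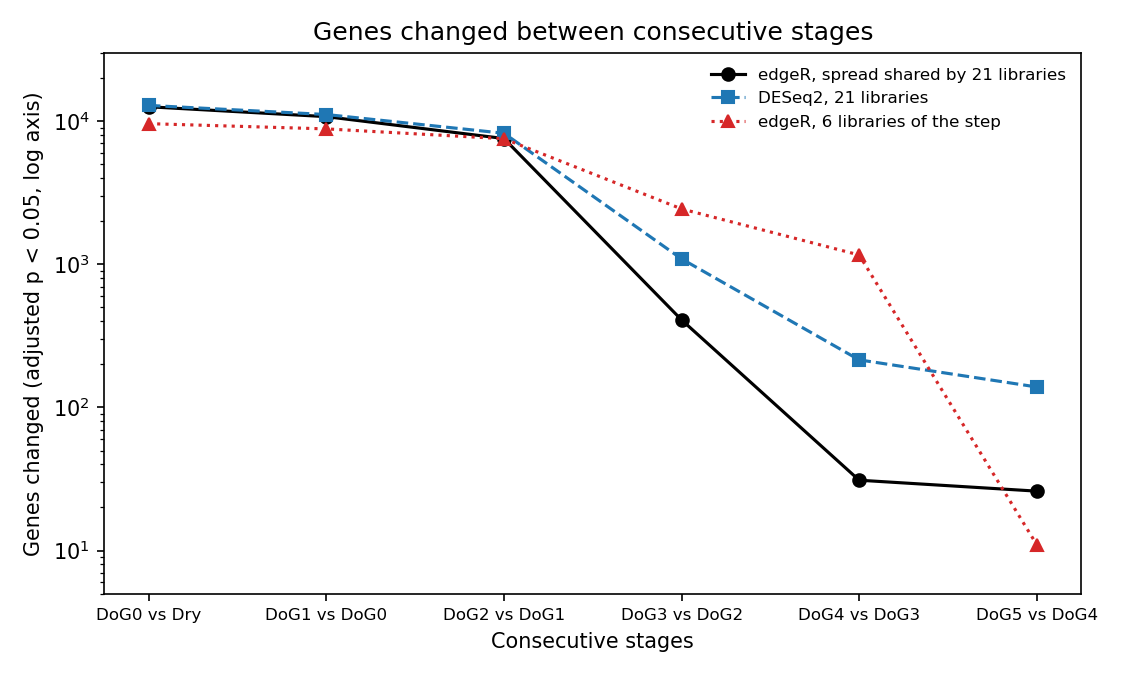
Genes changed at adjusted p under 0.05 (vertical, log axis) between consecutive stages (horizontal), for edgeR with a spread shared by 21 libraries (circles), DESeq2 (squares) and edgeR with the 6 libraries of the step (triangles). On the second day they give 7572, 8244 and 7552 genes, and on the fourth day 31, 215 and 1163.

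In comparisons added after the daily counts were seen, 2719 genes rose and 2594 fell between day 2 and day 5, 5313 in all, and 89 rose and 208 fell between day 3 and day 5, 297 in all. Leaving out DoG2 replicate B lowered the first count to 3439, and leaving out any 1 of its 6 libraries lowered the second to between 27 and 133. The majority of the second comparison turned in several settings: 52 genes rose and 34 fell by at least 2-fold, 76 rose and 43 fell with scaling by library size only, and 199 and 113 did with limma on log2(TPM + 1). With DESeq2 the second count was 1170.

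The germination phase as a whole was assessed by comparing day 5 with grain out of the steep. By then 7430 genes had risen and 6364 had fallen, 13794 or 66.8% of those tested. With the length trend removed 6978 rose and 7177 fell. At least 8-fold changes were seen in 1991 genes that rose and 556 that fell. HORVU.MOREX.r3.7HG0653340 fell from 288.5 ± 89.1 to 0.257 ± 0.0667 CPM (SD, n = 3 each; log2 fold change -10.08, SE 0.78, edgeR adjusted p = 6.5e-09).

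From dry grain to day 5, the whole process before drying in hot air, 7587 genes rose and 6713 fell, 14300 or 69.3% of those tested. Of these, 5330 rose and 3780 fell by at least 2-fold, and 1928 rose and 647 fell by at least 8-fold. Transcripts of 157 genes had no count in any dry library and at least 1 CPM at day 5, 16 of them at least 10 CPM, and 24 genes showed the reverse, 2 of them at 10 CPM or more. HORVU.MOREX.r3.7HG0747470 had no count in dry grain and 60.4 ± 10.3 CPM at day 5, at least 356-fold higher than a floor of 3 counts per dry library (edgeR adjusted p = 7.9e-09). HORVU.MOREX.r3.1HG0000260 went from 0.117 ± 0.117 CPM, 6 counts in all, to 285.6 ± 83.3 CPM (log2 fold change 11.25, SE 0.72, adjusted p = 1.16e-09). Its dry level lay under the floor of 3 counts per library, over which the day 5 level was 1685-fold, and the log2 fold change was 10.65 without Dry replicate A and 12.25 without Dry replicate B. HORVU.MOREX.r3.1HG0054710 fell to 4.76 ± 1.09 CPM (log2 fold change -9.64, SE 0.49, adjusted p = 1.67e-10), and -8.76 without Dry replicate A. HORVU.MOREX.r3.7HG0653340 fell from 167.8 ± 45.3 to 0.257 ± 0.0667 CPM (log2 fold change -9.30, SE 0.76, adjusted p = 1.52e-08; SD, n = 3 each). The libraries of both stages did not overlap for any of the 4, as the rule that chose them required. With scaling by library size only 9097 genes rose and 4962 fell, with limma on log2(TPM + 1) 10208 rose and 3329 fell, and with the length trend removed 6359 rose and 7689 fell. With only the 6 libraries of the 2 stages 10720 genes changed, and 10692 of the 14300 kept their call and direction.

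**Figure D5:**
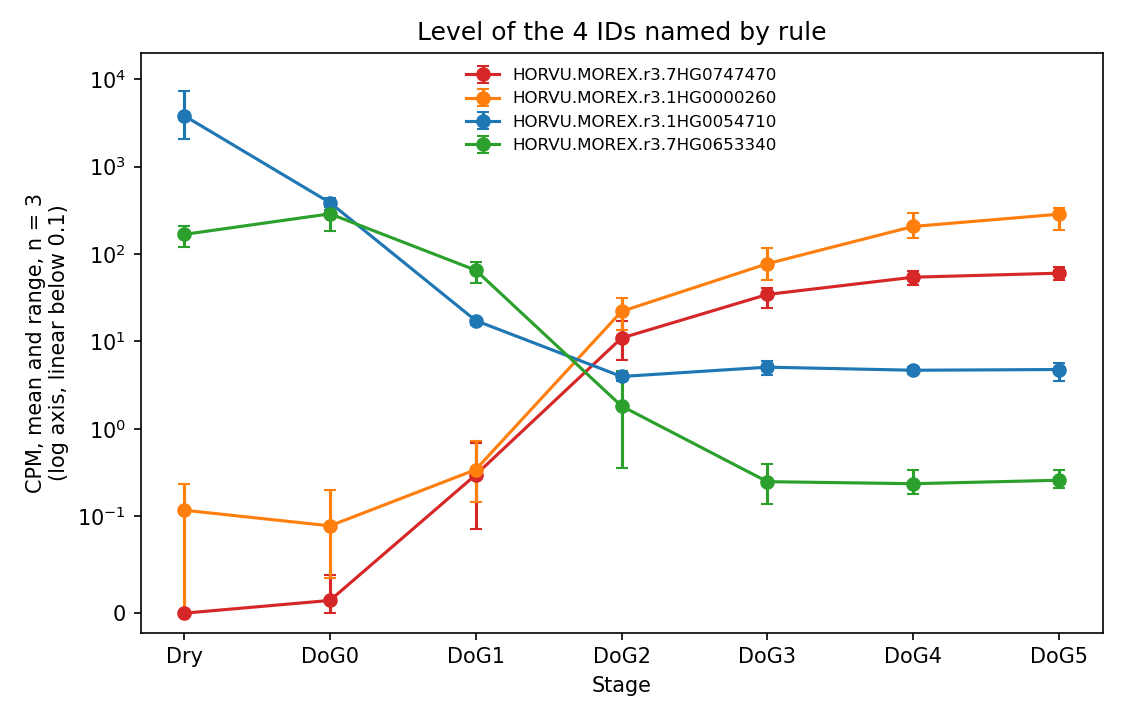
Level of the 4 named IDs (vertical, TMM-scaled CPM, log axis that is linear below 0.1) at the 7 stages (horizontal); points are means of 3 libraries and bars run from the lowest to the highest library. The rising pair reach 60.4 and 285.6 CPM at day 5, and the falling pair end at 4.76 and 0.257 CPM.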

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

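The length correction, the restriction to whole counts, the comparisons of day 5 with days 2 and 3, the groups by stage and the steeping groups on the second day were chosen only after the data were seen. The gene list tests and the share of TPM per gene list were not run, as IDs are not paired with names. Of 488 values, 33 are the reported ones, 379 stayed within 1.5 times of a count, within 1 SD or on the same side of the threshold, and 76 moved further. The 379 include the shares of the 10 most abundant genes with 1 library left out. These could not move by this rule, since leaving out 1 of 3 shifts a mean by under 1 SD. No fold change of a named ID turned its direction, but the majority among the changed genes did, in the comparisons named with those settings above and here, under library size only, limma on TPM, the length correction, no low-count filter, a minimum of 2-fold or a library left out. At steeping, 5984 rose and 5884 fell without DoG0 replicate A. A minimum of 2-fold left 7691 genes at steeping, 5426, 3932, 223 and 18 on days 1 to 4, 8769 from out-of-steep grain to day 5 and 9110 from dry grain to day 5, which follows from its construction. It left 2121 from day 2 to day 5, and 86 from day 3 to day 5, where 52 rose and 34 fell against 89 and 208. From day 2 to day 5 the majority turned without a filter (2293 rose, 2429 fell) and without DoG2 replicate A or C. On the third day the 6 libraries alone gave 1220 genes in each direction, and without DoG2 replicate A 65 rose and 66 fell. On days 3, 4 and 5 DESeq2 gave 1092, 215 and 139 genes against 409, 31 and 26, and the 6 libraries of the step alone gave 2440, 1163 and 11. The fourth day also gave 18 genes with library size only, 20 without a filter, 17 with limma on log2(TPM + 0.1) and 52 with limma without a filter, which gave 55 on the fifth day; the cause was not tested. Leaving out 1 library gave 79 (without DoG2 replicate C) to 174 (without DoG3 replicate A) genes on the third day, 1 (without DoG4 replicate B) to 8 (without DoG3 replicate C) on the fourth and 6 (without DoG4 replicate B) to 36 (without DoG5 replicate A) on the fifth, with fewer samples in each fit. It gave 11815 to 12511 genes at steeping, 8972 to 10708 on day 1 and 5863 to 7669 on day 2. To day 5 it gave 12792 to 13498 from out-of-steep and 13335 to 14258 from dry grain. Over the 7 stages, dropping 1 letter from each gave 16674 to 17761. With the letters as a replicate block 18787 genes changed over the 7 stages, 12427 at steeping, 10522, 7334, 275, 23 and 25 on days 1 to 5, and 13639 and 14121 from out-of-steep and dry grain to day 5, so no count moved by over 1.5 times. Deviations of libraries from their stage means showed no pairing by letter. Those with the same letter correlated between -0.295 and 0.157. In 0 of 8 comparisons were all 3 above 0.1, and 9 of 21 libraries correlated best with their own letter. Libraries of a stage also differed by length trends of their own, so this check cannot show that the letters are unpaired. The log2 fold changes of the 4 named IDs kept their direction and an adjusted p of at most 4.35e-07 under all 16 alternatives each. Limma on log2(TPM + 0.1) and limma without a filter gave 3167 and 3256 genes that rose at steeping and fell on the second day, 1263 and 1165 with the reverse, 2269 and 2585 highest in dry grain and 137 and 355 from day 3 to day 5. The share of the 10 most abundant genes by expected counts against TPM was 12.1% against 19.3% in dry grain, 6.71% against 8.21% out of the steep, and 4.48% against 4.73%, 5.53% against 6.38%, 5.07% against 6.10%, 4.90% against 6.25% and 4.40% against 6.04% on days 1 to 5, so the order of days 1 and 5 turned. At this depth 3 counts per library set a lower limit of 0.095 to 0.165 CPM by total count, and of 0.170 CPM on average in dry grain with TMM scaling.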

Other observations

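The tests on spread, on slow change, on the state of dry-grain RNA and on neighbouring IDs, and the counts of other splits, were chosen only after the results were seen; the tests on single libraries and on depth in the length trend were chosen after the trend but before their own values were seen.

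The 2371 genes highest at day 5 gained TPM share at each daily step from 3.53% ± 0.156 out of the steep, through 5.04% ± 0.477, 8.89% ± 0.438, 11.3% ± 0.273 and 13.7% ± 0.380, to 16.1% ± 0.317 (SD, n = 3 each). The genes highest at day 1 lost share over the same days, from 16.5% ± 0.805 to 10.1% ± 0.165, 8.62% ± 0.457, 7.75% ± 0.0412 and 7.11% ± 0.158. The genes highest at days 3 and 4 fell back after their peaks, to 8.25% ± 0.303 and 6.58% ± 0.250 at day 5. All these groups were chosen on these libraries, and each gene is bound by that choice to have its highest mean CPM at the stage of its group. The peak at day 5 and the falls after days 1, 3 and 4 follow from it at least in part. The values therefore describe the groups and test nothing.

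Replicates of the same stage differed from one another by length trends of their own, to a varying extent. Between DoG1 replicates A and C the Spearman correlation of the log2 ratio with transcript length was 0.328 across genes, and between DoG5 replicates A and C it was -0.320. The largest absolute value was 0.222 between dry libraries, 0.0886 between out-of-steep libraries and 0.143, 0.202 and 0.0916 between libraries of days 2, 3 and 4.

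Longer transcripts rose and shorter ones fell from dry to out-of-steep grain. A single odd library would leave some pairs of a dry and an out-of-steep library without the trend, and the lowest Spearman rho of the 9 pairs was 0.304. Lower depth of the dry libraries would lose the trend at equal depth, and with the 6 libraries thinned to 18783839 counts each rho was 0.377, against 0.369 before. A state of the RNA or of the library chemistry shared by the dry libraries may account for it, as all 6 later stages had the trend against dry grain, the lowest with rho 0.232, and dry libraries differed among themselves by up to 0.222. A biological change of the pool at steeping, which the stages name, predicts the same values and stays open too.

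Few genes changed per day after the second day. A larger spread between replicates does not account for the low counts of days 3 and 4. There the median SD of log2 CPM over the 2 stages of the step was 0.767 and 0.748 times that of the second-day step. On day 5 it was 1.00 times, but this averages an SD of 0.11 at day 4 with 0.21 at day 5, so spread is not ruled out there. The reported counts use one spread shared by all stages, which these ratios do not measure. The spread shared by all stages is not the whole cause either: with the 6 libraries of each step alone the highest of the 3 counts was 2440 genes, 0.323 times the 7552 of the second day, although it lies well above the 409 of the shared fit. Change that continued slowly over several days is a candidate explanation, since 5313 genes differed between day 2 and day 5, 11.4 times the sum of the 3 daily counts, against 4.29 times with DESeq2 and 1.70 times with the 6 libraries of each comparison. Within the last days the fits differ: between day 3 and day 5, against the fourth day alone, the counts were 297 and 31 in the shared fit and 1170 and 215 with DESeq2, but 444 and 1163 with 6 libraries.

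Genes with neighbouring IDs, in number order on the same chromosome code, changed together to a small extent. Over 20597 pairs the Spearman correlation of their log2 fold changes was lowest on the fourth day, 0.0641, and each of the 6 steps lay above the highest of 1000 shuffles of gene order within chromosome codes. If reads shared between similar genes were the only cause, genes with whole counts in all libraries would show no correlation. Among these genes the lowest was 0.0370 over 14405 pairs, against 0.0225 for the highest shuffle at that step. The correlation was lower than over all 20597 pairs at each of the 6 steps, so shared reads may account for part of it. Overlapping genes and local duplicates may still contribute, and no coordinates were used to test this. A shared regulation of neighbours stays an untested hypothesis.

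Other splits of the same libraries were counted for each comparison, with fits of the 6 libraries concerned. The 10 splits of 3 against 3 are too few for a share under 0.05. The real split was the 1 of 10 with the highest count in each of 10 comparisons: 9623 genes at steeping, 8844, 7552, 2440, 1163 and 11 on days 1 to 5, 12219 and 10720 from out-of-steep and dry grain to day 5, and 6155 from day 2 to day 5, where the highest other split gave 0, and 444 from day 3 to day 5, where it gave 5. For the 7 stages 1 of 40 splits, the real one with 18992 genes, gave as many, and the highest other split gave 1 gene. This is the smallest share that 40 splits can give. A split that mixes stages counts their differences as spread, so low counts in the other splits follow from the design. The splits therefore do not exclude chance.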
